A study of Mus musculus with 8 samples.

How the data were processed

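Gene expression was measured by RNA sequencing in 8 libraries of CD45-negative, CD31-negative stromal cells from the small intestine of indomethacin-treated mice, 4 YFP-positive and 4 YFP-negative. Per the labels' protocols, cells were sorted by flow cytometry into lysis buffer, libraries were made with Takara's low-input SMARTer kit for stranded total RNA, and sequencing was on an Illumina NextSeq. How the YFP reporter is expressed relative to Ltbr is not given in the sources used here. Per the submitters' processing notes, the tools were cutadapt 3.4, STAR 2.7.3a, featureCounts 2.0.1 and DESeq2, with the mouse build GRCm38. The notes give no order or settings for them, and the annotation release and the strand setting of the counting are not given in the sources used here. The deposited table lists raw counts per gene and library, per the file headers and the whole-number values. It also holds the authors' normalised values, a score in which each count was divided by a size factor and rounded, per the file headers; counts divided by DESeq2 size factors computed here differed from it by at most 0.499995. The authors' comparison in the same table holds log2 fold changes and p-values with adjusted p-values, per the file headers, with a fold change for 29762 genes and an adjusted p for 16502. Of the 53801 gene identifiers, 53620 had an entry in GENCODE M21, the annotation used here for GRCm38 coordinates, GC content, exon length and overlaps between genes.

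Everything tested here was computed from the deposited counts. Total counts per library ranged from 12481608 to 29385718, so that a gene at 1 CPM held about 12 counts in the smallest library. No libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 56.6), and Spearman correlations between libraries were 0.919 to 0.984. Groups and replicate numbers came from the sample titles. The comparison of YFP-positive with YFP-negative cells used edgeR 4.0.16 (R 4.3.3): filterByExpr by group, which left 15945 genes, TMM factors, a robust quasi-likelihood fit on group alone, a two-sided test and Benjamini-Hochberg adjustment, with genes called at an adjusted p of 0.05 or below. CPM values are TMM-normalised, and given as mean ± SD over 4 libraries. The test, the gene lists, the rule for named genes, the fit with the replicate number as a block and the other planned settings were chosen before the data were examined. The labels do not say whether the libraries are separate animals or whether equal numbers share a mouse, so p-values measure only the spread between these samples. The pairing was checked on the deviations of log2 CPM from the group means. Libraries of equal number correlated at 0.233, 0.487, 0.376 and 0.376, the highest correlation between different numbers across groups was 0.0456, and 8 of 8 libraries correlated best with their own number in the other group. The numbers were therefore taken to pair the samples from the data, not from the labels, and the value with the block is given beside each result whose call it changed.

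There were 46 gene lists with 703 entries, covering the lymphotoxin pathway, stromal and inflammatory programmes and markers of the cell types that an ulcer or the sort gate could hold. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, then with an estimated correlation and with fry, each adjusted over the lists. A list's median is that of the fit whose camera value stands beside it, and counts of list members that rose or fell are from the blocked edgeR fit. The file names Ccn1 and Ccn2 as Cyr61 and Ctgf, and Ca9 as Car9; Areg was taken by its identifier, to which the file gives another symbol; Ahsp was not analysed here. Where a symbol stood on more than one identifier, the lowest was taken. The naming rule took Ltbr and a fixed set of pathway, target and gate genes in every case. It then took, among called genes with an official symbol, a mean CPM of at least 5 and groups that do not overlap, the 10 with the largest change in each direction. From each list it took up to 2 called members in each direction with the lowest adjusted p, or else the most abundant members. Some genes that the rule took are not reported here. Without the block 0 genes qualified, so the rule was applied to the blocked fit, with the same direction in all 4 pairs in place of no overlap, which was decided after seeing the data. An exact two-sided permutation test of log2 CPM over the 70 assignments of 4 against 4 libraries was added for Ltbr; its smallest possible p is 0.0286.

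The planned settings were DESeq2 1.42.0, limma voom with quality weights, RLE and upper-quartile factors, library sizes alone, a looser and a stricter count filter (any count of at least 1; CPM of at least 2 in 4 libraries), mitochondrial genes or other cell types' markers left out. Also planned were an epithelium score as covariate, the block, and each library left out in turn. Those added after seeing the data were the same settings within the blocked fit, GC and length offsets, thinning to the smallest total, each pair left out, and the pairs of number 2 or 4 left out without the block. The edgeR steps were tested on simulated data drawn from the real means and library sizes of this comparison, with 15289 genes tested. Without the block, 0% of 67 genes changed 1.5-fold, 5.97% of 67 changed 2-fold and 74.2% of 66 changed 4-fold were recovered, with 0 false calls. With the block, the shares were 49.3%, 89.6% and 100%, with 12 false calls among 15731 unchanged genes simulated, of which those below the count filter were not tested. Apart from the simulated changes, both libraries of a number were given the same expected level, and the dispersions came from the blocked fit. The simulation thus takes the pairing as exact, so the better recovery with the block is partly built in. A list shifted by -0.6 on the log2 scale was recovered by camera in both fits, with 0 of 41 other lists called, and with an estimated correlation it was recovered with the block (adjusted p = 0.0466) and not without it (adjusted p = 0.174). Each gene was drawn independently, so the simulation does not check false list calls where the members of a list move together. The offsets reduced a simulated GC slope of 0.3 from 0.299 to 0.0101. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.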

Results

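Stromal cells lacking the leukocyte marker CD45 and the endothelial marker CD31 were sorted from small-intestinal ulcers of LTβR-YFP reporter mice that had been given indomethacin, a cyclooxygenase inhibitor that injures the small intestine. The sort separated a YFP-positive from a YFP-negative fraction, and the total RNA of each was sequenced. The series held 4 YFP-positive and 4 YFP-negative libraries, numbered 1 to 4 in each group. Total counts in genes were 18582584, 12481608, 28931436 and 20894653 in YFP-negative replicates 1 to 4. They were 29385718, 14564835, 23461608 and 23656792 in YFP-positive replicates 1 to 4. Of the 53801 genes listed, 15945 passed the count filter and were tested. The libraries of replicate number 2 stood apart from the rest on the first principal component, which held 35.5% of the variance: they lay at 92.5 (YFP-negative) and 78.7 (YFP-positive), and the other libraries between -46.2 and -12.4. Mitochondrially encoded genes took a lower share of the counts in the YFP-positive library of 4 of 4 pairs of equal replicate number, at 7.98% against 8.27%, 7.99% against 8.75%, 7.71% against 8.07% and 9.43% against 12.4%.

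**Figure D1:**
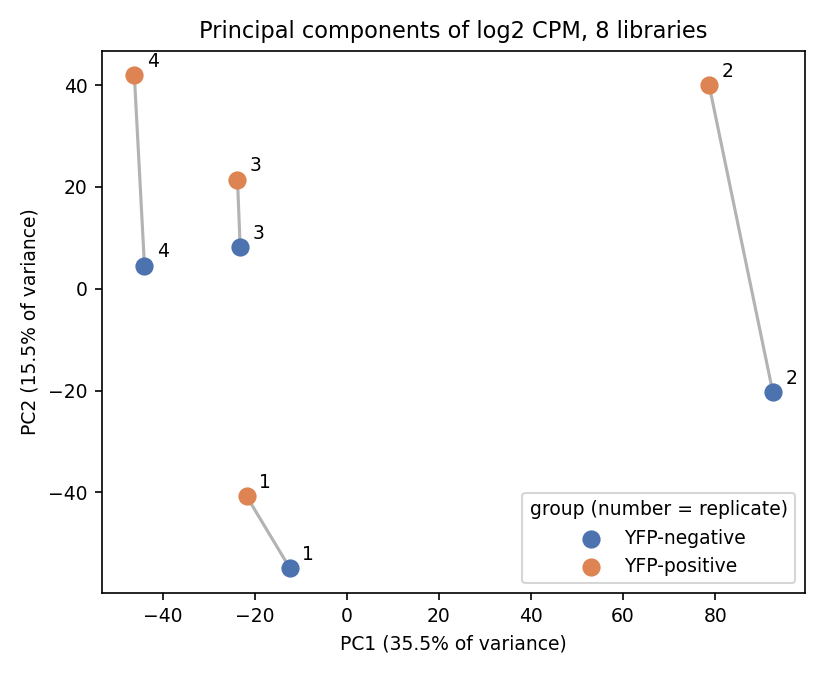
First and second principal components (35.5% and 15.5% of the variance) of log2 CPM in the 8 libraries, coloured by group, with a line joining the libraries of equal replicate number. Both libraries of replicate number 2 lie at 78.7 or above on the first component, and the others lie below 0.

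The comparison asked how stromal cells that carried the YFP reporter differed from those that did not. With a preset correlation between genes, camera called markers of adventitial fibroblasts and interstitial matrix genes lower in YFP-positive cells, and markers of subepithelial fibroblasts and smooth muscle higher. None of these 4 lists was called with an estimated correlation or by fry, and not all of their members passed on their own. Ackr4, a receptor that scavenges the chemokines CCL19, CCL21 and CCL25, fell from 72.2 ± 13.1 CPM (counts normalised to library size; mean ± SD, n = 4) in YFP-negative to 36.6 ± 9.18 CPM in YFP-positive cells. C3, the central component of complement, fell from 13203 ± 1914 to 8250 ± 1328 CPM (n = 4). Ednrb, the endothelin type B receptor, rose from 209 ± 49.7 to 313 ± 61.3 CPM (n = 4), and Myh11, the smooth muscle myosin heavy chain, rose from 199 ± 62.4 to 280 ± 103 CPM (n = 4). These 4 genes changed in the same direction in 4 of 4 pairs. They were picked from their lists for a low adjusted p in the blocked fit, so this agreement is no separate support. They passed the test only with the replicate number as a block (adjusted p = 5.9e-05, 8.0e-05, 1.4e-04 and 0.00247, edgeR).

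The planned edgeR test, which had no block, called 0 genes higher and 0 lower in YFP-positive cells (lowest adjusted p = 0.99985); at an unadjusted p of 0.05, 156 genes were higher and 169 lower. In 110 genes every YFP-positive library lay above every YFP-negative library and in 137 below, 1.55% of those tested. Chance gives 2.86% if the libraries are assigned freely, a share that does not allow for the pairing by replicate number. DESeq2 without a block called 0 genes higher and 2 lower, Gfap and 4930533B01Rik, which are named here because the count is small and were chosen after their values were seen. YFP-negative replicate 1 held 172 of the 286 YFP-negative counts of Gfap and 74 of the 243 of 4930533B01Rik. With the replicate number as a block, edgeR called 111 genes higher and 253 lower, of which 8 and 14 had an absolute log2 fold change of at least 1. DESeq2 with the block called 155 higher and 341 lower. The split between directions depended on the scaling. With library sizes alone, the blocked fit called 212 genes higher and 153 lower, of which 110 and 151 were also called with TMM factors. Without both libraries of replicate number 1, 2, 3 or 4, the blocked fit called 73, 130, 38 and 47 genes higher and 121, 296, 119 and 120 lower. Of the 45 gene lists with a tested member, camera called 7 higher and 9 lower without the block and 12 higher and 14 lower with it; with an estimated correlation it called 0 in either fit. Every "rose" or "fell" of a gene in the following paragraphs refers to the blocked edgeR fit. Adjusted over all genes tested, the unblocked fit called none of them.

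Ltbr itself, which encodes the lymphotoxin beta receptor (ENSMUSG00000030339, GRCm38 chromosome 6, 125306571 to 125313885, minus strand), stood at 71.3 ± 13.8 CPM in YFP-negative and 79.7 ± 14.1 CPM in YFP-positive cells (n = 4). The log2 fold change was 0.16, with a 95% confidence interval of -0.27 to 0.59, and 2 of 4 pairs were higher in the YFP-positive library (exact two-sided permutation p = 0.457; adjusted p = 0.99985 without and 0.613 with the block, edgeR). The interval with the block spanned a 0.972-fold to a 1.29-fold level. The group difference in Ltbr was therefore smaller than the spread between replicates. None of the other genes fixed for the receptor's pathway and targets passed either edgeR fit. In the authors' deposited table, 3 of them did: Nfkb2, Icam1 and Madcam1 had an adjusted p of 0.0481, 0.00161 and 0.0403. Nfkb2 and Icam1 were lower in the YFP-positive library of 4 of 4 pairs. Nfkb2 and Relb, the subunits of the noncanonical NF-kB dimer, were at 130 ± 41.1 and 70.6 ± 24.1 CPM in YFP-negative and at 109 ± 40.6 and 62.3 ± 18.2 CPM in YFP-positive cells (n = 4; blocked adjusted p = 0.0808 and 0.627, edgeR). Map3k14, the NF-kB-inducing kinase, was at 31.8 ± 10.8 and 33.0 ± 6.10 CPM (n = 4), and the difference turned to a log2 fold change of -0.17 without YFP-negative replicate 1. The adhesion genes Icam1 and Vcam1 were at 746 ± 301 and 221 ± 46.7 CPM in YFP-negative and at 602 ± 281 and 203 ± 23.6 CPM in YFP-positive cells (n = 4; blocked adjusted p = 0.0718 and 0.688, edgeR). The chemokine gene Cxcl13 was at 431 ± 341 and 378 ± 257 CPM and the podoplanin gene Pdpn at 428 ± 111 and 400 ± 128 CPM (n = 4). Cxcl13 was lower in 4 of 4 pairs (blocked adjusted p = 0.546, edgeR). Without the block, leaving out single libraries turned the direction in 1 case for Vcam1, 2 for Cxcl13 and 4 for Pdpn. Their log2 fold changes reached 0.0053 without YFP-negative replicate 1, 0.50 without YFP-negative replicate 3 and 0.028 without YFP-positive replicate 3. Madcam1, a mucosal addressin, was low in both groups, at 0.539 ± 0.370 and 3.80 ± 3.84 CPM (n = 4; log2 fold change 2.46, blocked adjusted p = 0.285, edgeR). Ccl19 had 4 counts in the YFP-negative and 18 in the YFP-positive libraries and was too low to test.

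**Figure D2:**
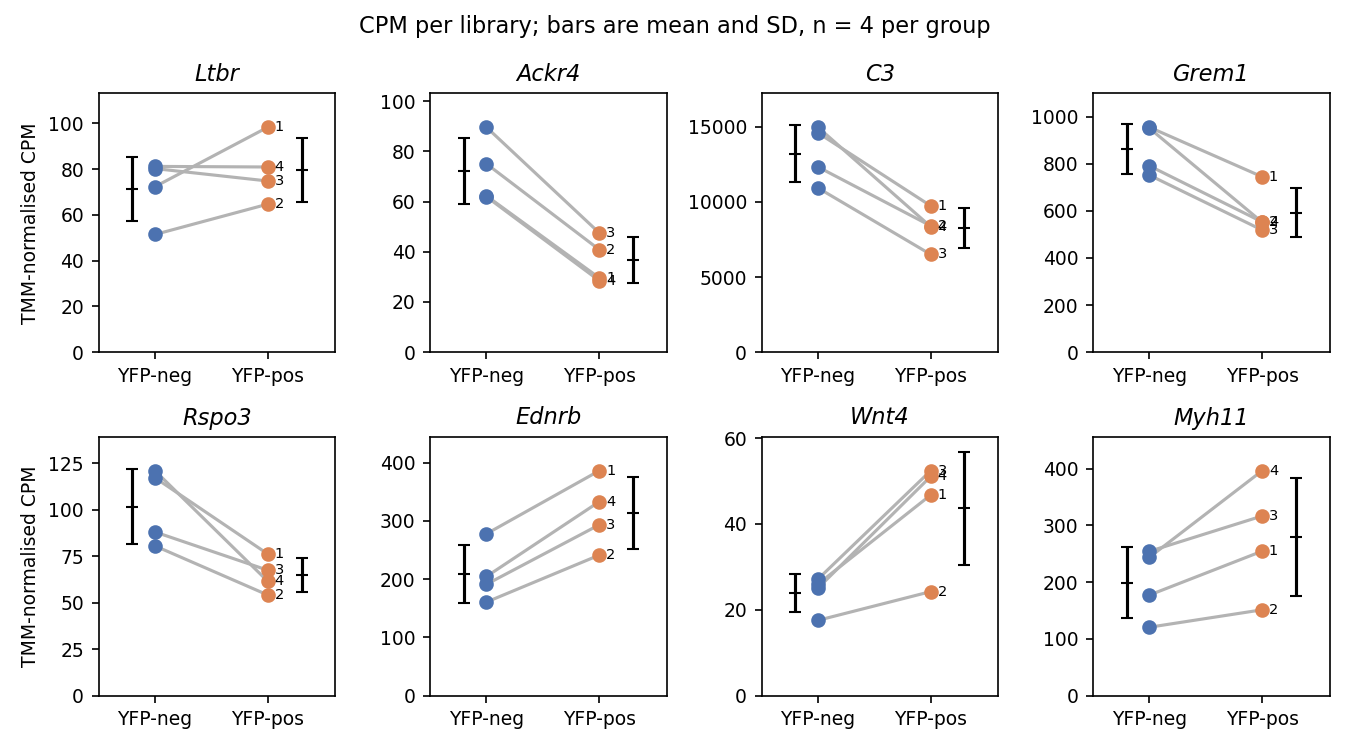
Normalised CPM of 8 genes in each library, with a line joining the YFP-negative and YFP-positive libraries of equal replicate number and bars for the mean and SD of each group (n = 4). Ltbr is higher in the YFP-positive library of 2 of 4 pairs. Ackr4, C3, Grem1 and Rspo3 are lower, and Ednrb, Wnt4 and Myh11 higher, in 4 of 4 pairs. Apart from Ltbr, the genes were picked for a low adjusted p in the blocked fit.

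Genes were also named by the size of their change in the blocked fit. Rapgef5, an exchange factor for Rap GTPases (ENSMUSG00000041992, chromosome 12, 117516479 to 117759737, plus strand), rose from 1.46 ± 1.32 to 12.6 ± 14.2 CPM (n = 4), a log2 fold change of 2.95 ± 0.360 (SE; adjusted p = 3.1e-04, edgeR). The protein kinase C gene Prkch, the calcium release channel Ryr3, the smooth muscle actin nucleator Lmod1 and the junction gene Cxadr rose by log2 fold changes of 1.70, 1.22, 1.00 and 0.97. The vesicle protein Sv2b, Ano5, the G protein subunit Gng2, the ATP-gated channel P2rx1 and the phosphodiesterase Pde8b rose by 0.95, 0.95, 0.91, 0.91 and 0.89. The matrix metalloproteinase gene Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499, plus strand) fell from 14.7 ± 9.87 to 4.83 ± 3.19 CPM (n = 4), a log2 fold change of -1.70 ± 0.295 (SE; adjusted p = 0.00647, edgeR). The procollagen processing enhancer Pcolce2, the pentraxin Ptx3, the Wnt amplifier Rspo2 and Rasgef1c fell, with log2 fold changes of -1.43, -1.27, -1.25 and -1.24. So did the thyroid hormone transporter Slco1c1, Pianp, the neurotrophin receptor Ntrk2 and the sulphate donor synthase Papss2, at -1.06, -1.04, -1.02 and -1.01. All of these changed in the same direction in 4 of 4 pairs, which the naming rule required. Rapgef5, Sv2b, P2rx1, Rasgef1c, Ntrk2 and Papss2 passed in all 15 other blocked settings, and none of the genes turned in direction in any. The others lost their call in 1 to 6 of those settings, with the highest adjusted p at 0.320 for Pde8b without replicate 4 (edgeR). Reads of an annotated gene on the opposite strand cannot be excluded for Ryr3, Cxadr, Sv2b, Gng2, Pde8b and Mmp12, because the strand setting of the counting is not given in the sources used here.

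Fibroblast marker lists changed in both directions, in pairs whose YFP-positive library also had lower enteric glia markers, higher pan-leukocyte markers and a lower mitochondrial share (each in 4 of 4). Of 14 tested markers of adventitial fibroblasts and trophocytes, the CD81-positive cells that secrete Grem1, 9 fell and 0 rose (adjusted over the list alone, 11 fell), with a median log2 fold change of -0.60 without the block. They included Ackr4 (ENSMUSG00000079355, chromosome 9, 104084157 to 104126933, minus strand) and C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136, minus strand). The BMP antagonist Grem1 fell from 862 ± 106 to 592 ± 103 CPM, and the Wnt amplifier Rspo3 from 102 ± 20.4 to 64.8 ± 9.33 CPM (n = 4). The list was lower than other genes in the planned test (camera adjusted p = 1.2e-11) but not with the correlation between its genes estimated (adjusted p = 0.199 with an estimated correlation). Of 13 tested markers of subepithelial fibroblasts with high Pdgfra, 6 rose and 0 fell (adjusted over the list alone, 8 rose). Their median log2 fold change was 0.30 (camera adjusted p = 4.8e-04; adjusted p = 0.199 with an estimated correlation). Ednrb (ENSMUSG00000022122, chromosome 14, 103814625 to 103844402, minus strand) and Bmp5, a bone morphogenetic protein (210 ± 47.8 to 280 ± 65.6 CPM, n = 4), had the lowest adjusted p among its members that rose, at 1.4e-04 and 0.00216 (edgeR). Of 12 pan-fibroblast markers, 8 fell and 0 rose (8 adjusted over the list alone; median log2 fold change -0.42; camera adjusted p = 5.4e-05; adjusted p = 0.199 with an estimated correlation). These 3 lists share members with other lists: 6 of the 14, 7 of the 13 and 11 of the 12 genes stand in another list too. Among the lists given below, so do 7 of 25 interstitial matrix genes, 6 of 21 Wnt, R-spondin and BMP genes and 3 of 15 complement genes. Results of lists that share genes are not independent. Ackr4, Bmp5 and Rspo3 overlap an annotated gene on the opposite strand.

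Some genes of the interstitial matrix fell, and a few of the basement membrane rose; the difference between the lists was not tested. Of 25 tested genes for fibrillar collagens and interstitial matrix proteins, 13 fell and 0 rose (adjusted over the list alone, 16 fell and 3 rose). Lum, the proteoglycan lumican, fell from 1012 ± 316 to 616 ± 144 CPM, and Fbln1, the matrix glycoprotein fibulin 1, from 971 ± 329 to 601 ± 224 CPM (n = 4; both blocked adjusted p = 7.8e-05, edgeR). The median of the list was -0.29 on the log2 scale (camera adjusted p = 2.9e-05; adjusted p = 0.436 with an estimated correlation). Of 16 basement membrane genes, 3 rose and 0 fell (adjusted over the list alone, 7 rose and 1 fell). Col18a1, the precursor of endostatin, rose from 1380 ± 323 to 1977 ± 676 CPM, and Col4a6 rose from 23.6 ± 8.0 to 36.4 ± 12.6 CPM (n = 4). The basement membrane list, with a median log2 fold change of 0.15, was called with the block (camera adjusted p = 0.00309; adjusted p = 0.245 with an estimated correlation) and not without it (adjusted p = 0.126). The blocked call ended without replicate 3 (adjusted p = 0.0505). Of 23 matrix remodelling genes, 2 rose and 4 fell (adjusted over the list alone, 3 and 9). Mmp10, or stromelysin 2, rose from 762 ± 425 to 1141 ± 632 CPM, and the urokinase gene Plau from 128 ± 69.4 to 176 ± 115 CPM (n = 4). Adamts2, a procollagen N-proteinase, fell from 348 ± 72.7 to 252 ± 51.5 CPM (n = 4). That list, with a median of -0.12, was called lower only with the block (camera adjusted p = 0.00710 against 0.107 without; adjusted p = 0.278 with an estimated correlation). It lost the call with library sizes alone (0.105) and without replicate 4 (0.0662). Col4a6 and Plau lost their calls in 2 settings each, with the highest adjusted p at 0.117 and 0.0856 (edgeR).

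Of 12 smooth muscle genes, 3 rose and 0 fell (adjusted over the list alone, 9 rose), with a median log2 fold change of 0.32 (camera adjusted p = 2.9e-05; adjusted p = 0.436 with an estimated correlation). Next to Myh11 (ENSMUSG00000018830, chromosome 16, 14194535 to 14291372, minus strand), the smooth muscle actin gene Acta2 rose from 188 ± 67.5 to 256 ± 114 CPM (n = 4; blocked adjusted p = 0.00387, edgeR). Of 20 TGF-beta and contractile myofibroblast genes, 2 rose and 1 fell (adjusted over the list alone, 7 and 5). Besides Acta2, the tropomyosin Tpm2 rose from 93.5 ± 25.4 to 124 ± 23.9 CPM, and the ligand Tgfb3 fell from 71.6 ± 28.3 to 49.6 ± 12.9 CPM (n = 4). The list was called higher with the block by a median of 0.08 (camera adjusted p = 0.0417; adjusted p = 0.249 with an estimated correlation) and not without it (adjusted p = 0.465). It lost the blocked call in 5 settings, replicate 1 or 3 left out among them (adjusted p = 0.0511 to 0.0775). Of 10 pericyte genes, 1 rose and 1 fell (adjusted over the list alone, 3 and 2). The proteoglycan gene Cspg4 rose from 114 ± 30.2 to 152 ± 27.3 CPM, and Rgs5 fell from 1140 ± 196 to 886 ± 143 CPM (n = 4). The pericyte list was not called (camera adjusted p = 0.941 without and 0.743 with the block). Of 7 markers of interstitial cells of Cajal, the connexin Gja1 rose from 425 ± 79.3 to 596 ± 118 CPM (n = 4) and none fell (adjusted over the list alone, 1 and 0). That list was not called either (camera adjusted p = 0.842 and 0.116). Tpm2 and Cspg4 lost their calls without replicate 1 (adjusted p = 0.0502 and 0.05003), Rgs5 without replicate 3 (0.0508) and Tgfb3 in 3 settings (up to 0.126 without replicate 4; edgeR).

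Some genes of inflammatory programmes were lower in YFP-positive cells with the block. The mitochondrial share and the immediate early list were also lower, and pan-leukocyte markers higher, in 4 of 4 pairs. Of 15 complement genes, 5 fell and 0 rose (adjusted over the list alone, 7 fell), C3 among them. The complement list had a median of -0.17 (camera adjusted p = 0.00360; adjusted p = 0.199 with an estimated correlation). Of 18 genes of LTβR and noncanonical NF-kB signalling, 2 fell and 0 rose (adjusted over the list alone, 7 fell). They were the feedback inhibitor Tnfaip3, which fell from 954 ± 366 to 729 ± 320 CPM, and the inhibitory subunit Nfkbie, which fell from 96.2 ± 17.2 to 76.3 ± 23.1 CPM (n = 4; blocked adjusted p = 0.0128 and 0.0486, edgeR). Ltbr and Map3k14 had blocked log2 fold changes of 0.16 and 0.11, and the noncanonical subunits Nfkb2 and Relb of -0.27 and -0.16. None of these was called, so the list's fall is not one of the receptor's noncanonical arm alone. The list had a median of -0.16 (camera adjusted p = 0.0269; adjusted p = 0.545 with an estimated correlation). It lost its call with library sizes alone and without YFP-negative replicate 1 or 2 or YFP-positive replicate 3 or 4 or both of number 4 (adjusted p = 0.0645 to 0.653). With the block the call held at an adjusted p of 2.1e-05 (adjusted p = 0.249 with an estimated correlation). Of 25 inflammatory cytokine and chemokine genes, 3 fell and 0 rose (adjusted over the list alone, 6 fell and 1 rose), among them Il6 (599 ± 258 to 426 ± 221 CPM) and Cxcl10 (138 ± 75.0 to 99.8 ± 54.0 CPM, n = 4). This list was called only with the block (median -0.07; camera adjusted p = 0.00491 against 0.158 without; adjusted p = 0.206 with an estimated correlation). Of 15 lymphoid stromal organiser genes, 4 fell and 0 rose (adjusted over the list alone, 5 fell and 3 rose). Il33, an alarmin, fell from 279 ± 63.7 to 191 ± 39.4 CPM and the chemokine gene Cxcl12 from 827 ± 220 to 652 ± 163 CPM (n = 4). The list's median (-0.11) and mean (0.16) differ in sign, and its mean log2 CPM was higher in the YFP-positive library of 3 of 4 pairs. It was called lower with the block (camera adjusted p = 0.0317; adjusted p = 0.278 with an estimated correlation) and not without it (0.522). It lost the blocked call with library sizes alone or without replicate 2 or 3 (adjusted p = 0.0667 to 0.0849). Tnfaip3, Il6 and Cxcl10 lost their calls in 1, 2 and 3 settings, each without replicate 1 (adjusted p = 0.0865, 0.104 and 0.109), Cxcl12 without replicate 3 (0.0881) and Nfkbie in 7 settings (up to 0.320 without replicate 4; edgeR).

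Of 25 interferon response genes, 0 rose and 0 fell, also when adjusted over the list alone. The most abundant, Ifitm3 and Ifitm1, were at 306 ± 47.1 and 296 ± 59.1 CPM in YFP-negative and at 299 ± 53.3 and 300.0 ± 66.9 CPM in YFP-positive cells (n = 4). The list as a whole was lower by a median of -0.13 (camera adjusted p = 0.0249; adjusted p = 0.634 with an estimated correlation). The call ended with no filter, with voom weights and without YFP-negative replicate 1 or 3, YFP-positive replicate 2 or 4 or both of number 2 (adjusted p = 0.0766 to 0.854), and the median was 0.010 without YFP-negative replicate 3. Of 10 MHC class II genes, 0 passed in either direction, also adjusted over the list alone, and the list was higher by a median of 0.76 (camera adjusted p = 0.00189; adjusted p = 0.436 with an estimated correlation). Cd74, the invariant chain, was at 16.8 ± 2.99 and 29.0 ± 17.0 CPM (n = 4), and the list's call ended with voom weights, without YFP-positive replicate 2 and without both of number 2 (adjusted p = 0.0675 to 0.202). Of 24 immediate early and heat shock genes, 4 fell and 0 rose (adjusted over the list alone, 14 fell), with a median of -0.25 (camera adjusted p = 9.0e-05; adjusted p = 0.634 with an estimated correlation). The chaperone gene Dnajb1 fell from 204 ± 48.5 to 147 ± 38.3 CPM and the transcription factor gene Egr3 from 81.9 ± 29.7 to 63.8 ± 26.8 CPM (n = 4). The immediate early list lost its unblocked call without YFP-negative replicate 2 (median -0.03, adjusted p = 0.533) and without YFP-positive replicate 4 (median -0.06, adjusted p = 0.679). It moved with the mitochondrial share, which was also lower in 4 of 4 pairs. Of 7 mitochondrially encoded mRNAs, mt-Co1 fell from 1837 ± 353 to 1507 ± 131 CPM (n = 4) and none rose (adjusted over the list alone, 7 fell). Their median was -0.22 (camera adjusted p = 0.00446; adjusted p = 0.548 with an estimated correlation), and the call ended with no filter (0.0975) and without YFP-negative replicate 4 (0.392), YFP-positive replicate 3 (0.222) or both of number 4 (0.0930). Of 7 nuclear-retained and long noncoding RNAs, 2 fell and 0 rose (3 fell adjusted over the list alone). Rian fell from 118 ± 49.3 to 71.4 ± 20.4 CPM and Meg3 from 129 ± 48.9 to 89.9 ± 25.1 CPM (n = 4). Both come from the same imprinted locus and overlap annotated neighbours on the same strand, so their counts are uncertain. That list, at a median of -0.36, was called with the block (camera adjusted p = 2.7e-05; adjusted p = 0.206 with an estimated correlation) and not without it (0.0521). Dnajb1, Egr3, mt-Co1 and Meg3 lost their calls in 3, 5, 7 and 3 settings, with the highest adjusted p at 0.164, 0.207, 0.226 and 0.0926 (edgeR).

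**Figure D3:**
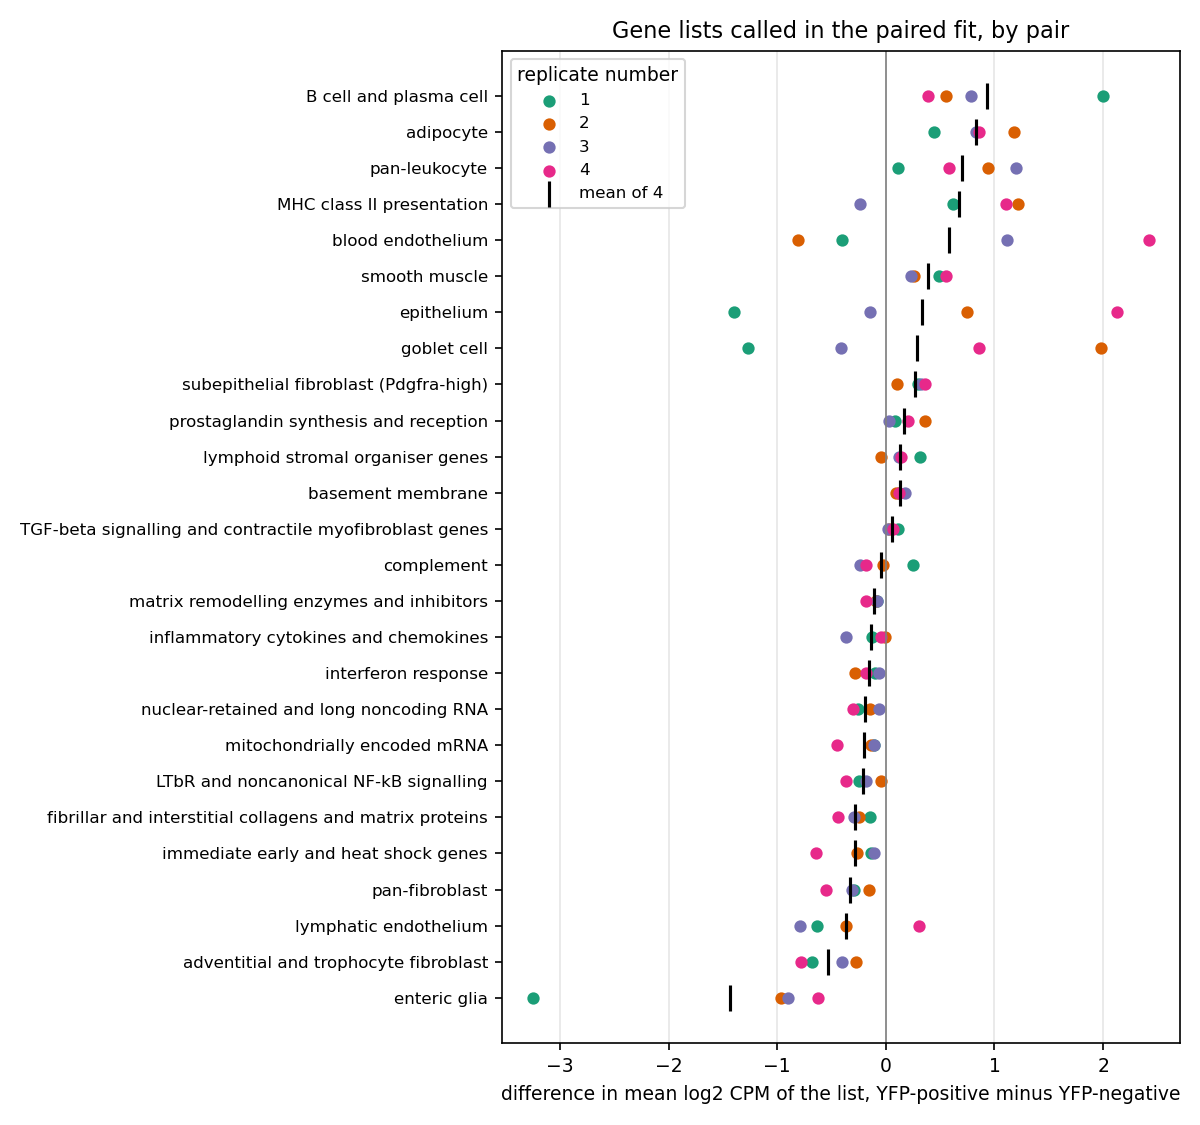
Difference in the mean log2 CPM of each gene list called with the block, YFP-positive minus YFP-negative library, for each of the 4 replicate numbers, with the mean of the 4 as a bar. Subepithelial fibroblast and smooth muscle lists lie above 0, and adventitial fibroblast, pan-fibroblast and interstitial collagen lists below 0, in 4 of 4 pairs; epithelium, goblet cell and blood endothelium lists lie above 0 in 2 of 4. Of the lists called lower, lymphoid organiser genes lie above 0 in 3 of 4 and complement and lymphatic endothelium in 1 of 4; MHC class II genes, called higher, do so in 3 of 4.

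Niche factors for the epithelium changed in both directions. Of 21 Wnt, R-spondin and BMP genes, 4 rose and 6 fell (adjusted over the list alone, 7 and 8). Wnt4 (ENSMUSG00000036856, chromosome 4, 137277489 to 137299726, plus strand) rose from 23.9 ± 4.34 to 43.6 ± 13.1 CPM (n = 4), a log2 fold change of 0.83 ± 0.121 (SE; adjusted p = 0.00132, edgeR). Bmp5 rose too, and Grem1 and Rspo3 were among those that fell. The list as a whole was not called (camera adjusted p = 0.186 without and 0.117 with the block; median -0.06 with the block). Of 17 retinoic acid genes, 2 rose and 1 fell (3 and 1 adjusted over the list alone). The synthesis enzymes Aldh1a2 and Rdh10 rose from 279 ± 72.2 to 357 ± 104 CPM and from 181 ± 49.8 to 225 ± 59.8 CPM (n = 4). The list was not called (camera adjusted p = 0.582 and 0.188). Of 16 prostaglandin genes, 1 rose and 1 fell (2 and 1 adjusted over the list alone). Ptgs1, which encodes cyclooxygenase 1, an indomethacin target, rose from 121 ± 25.5 to 163 ± 36.4 CPM (n = 4). Hpgd, the enzyme that inactivates prostaglandins, fell from 27.2 ± 8.47 to 17.1 ± 5.10 CPM (n = 4). The prostaglandin list was called higher with the block (median 0.15; camera adjusted p = 0.0443; adjusted p = 0.249 with an estimated correlation) and not without it (0.141). It lost the blocked call with the stricter filter, after thinning and without replicate 1, 2 or 3 (adjusted p = 0.0502 to 0.0890). Of 23 growth factor genes of angiogenesis and repair, 2 rose and 3 fell (3 and 5 adjusted over the list alone), and the list was not called (camera adjusted p = 0.437 and 0.816). The ErbB ligand Nrg1 rose from 794 ± 150 to 1060 ± 140 CPM and the fibroblast growth factor Fgf10 from 27.4 ± 8.83 to 41.0 ± 16.8 CPM (n = 4). The lymphangiogenic ligand Vegfd fell from 27.4 ± 4.31 to 15.2 ± 3.21 CPM (n = 4). Without replicate 3, the calls of Aldh1a2, Rdh10, Ptgs1 and Nrg1 ended (adjusted p = 0.0630, 0.263, 0.0579 and 0.110; edgeR). That of Hpgd ended without replicate 1 (0.163) and those of Fgf10 and Vegfd without replicate 4 (0.121 and 0.0565; edgeR). Of the 15 other blocked settings, Rdh10, Hpgd, Fgf10 and Vegfd lost their calls in 5, 4, 3 and 2, these included. Ptgs1, Nrg1, Fgf10, Cxcl10, Tgfb3, mt-Co1, Nfkb2, Icam1 and Vcam1 overlap an annotated gene on the opposite strand, and Map3k14 and Cd74 an annotated gene on the same strand, so their counts are uncertain.

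Markers of other cell types were measured beside these genes. Enteric glia markers were lower in the YFP-positive library of 4 of 4 pairs, with a median of -1.69 over 7 tested genes (camera adjusted p = 2.9e-05; adjusted p = 0.199 with an estimated correlation). Of those 7, 1 fell and 0 rose (3 fell adjusted over the list alone); Gpm6b, the most abundant, was at 283 ± 49.0 and 274 ± 37.3 CPM. The blocked call of the glia list ended without replicate 1 (median -0.35, adjusted p = 0.0775). Pan-leukocyte markers were higher by a median of 0.52 over 10 genes (camera adjusted p = 9.0e-05; adjusted p = 0.436 with an estimated correlation), with 0 genes called in either direction (2 rose adjusted over the list alone). The call ended without YFP-negative replicate 3 (0.261). Ptprc, which encodes CD45, was at 2.60 ± 1.57 and 5.52 ± 4.68 CPM (n = 4; blocked adjusted p = 0.513, edgeR). Markers of B and plasma cells were higher by a median of 0.93 over 6 genes (camera adjusted p = 0.0143; adjusted p = 0.436 with an estimated correlation), with 0 genes called. The immunoglobulin gene Igha was at 60.7 ± 57.8 and 141 ± 103 CPM (n = 4), and the call ended with either other filter, with voom weights and without YFP-negative replicate 1 or 3 or YFP-positive replicate 4 (adjusted p = 0.0581 to 0.344). Blood endothelium markers were higher by a median of 1.13 over 11 genes, with 0 called (camera adjusted p = 0.0156; adjusted p = 0.634 with an estimated correlation). The list was higher in 2 of 4 pairs, and Pecam1, which encodes CD31, was at 25.9 ± 16.3 and 28.6 ± 14.5 CPM (n = 4). That call rested on YFP-positive replicate 4, without which the median was 0.08 (adjusted p = 0.821). Epithelium markers, with Epcam at 1.25 ± 1.24 and 5.48 ± 8.63 CPM (n = 4), were called higher only with the block, with 0 of 10 genes called. Their median was 0.39 (camera adjusted p = 1.8e-05 against 0.496 without; adjusted p = 0.206 with an estimated correlation). The list was higher in 2 of 4 pairs, and the median turned to -0.49 without replicate 4 (adjusted p = 0.165). Goblet cell markers were also called higher only with the block (median 0.43 over 4 genes, 0 of them called; camera adjusted p = 0.0141 against 0.842 without; adjusted p = 0.245 with an estimated correlation). Without replicate 4 the test turned to lower, at a median of 0.14 (adjusted p = 0.664).

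**Figure D4:**
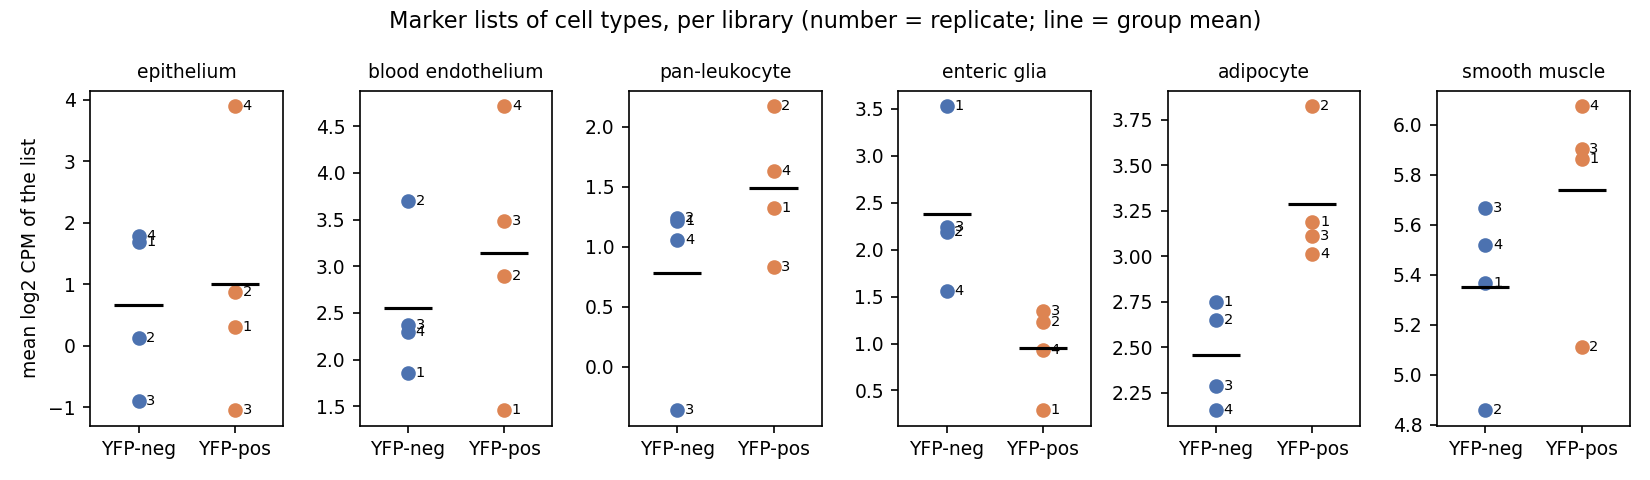
Mean log2 CPM of 6 marker lists in each library, with the replicate number beside each point and a line at the group mean (n = 4). Epithelium and blood endothelium markers are highest in YFP-positive replicate 4, and enteric glia markers are highest in YFP-negative replicate 1.

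Adipocyte markers were higher with the block (median 1.14 over 4 genes; camera adjusted p = 0.00124; adjusted p = 0.206 with an estimated correlation; adjusted p = 0.115 without it). Of these, the lipoprotein lipase gene Lpl, which fibroblasts also express, rose from 155 ± 99.8 to 254 ± 160 CPM (n = 4; blocked adjusted p = 7.8e-05, edgeR), and none fell (2 rose adjusted over the list alone). Pparg, another member, was at 16.4 ± 6.68 and 16.5 ± 4.85 CPM (n = 4), with a blocked log2 fold change of 0.018 (adjusted p = 0.992, edgeR). Lymphatic endothelium markers were lower with the block (median -0.26 over 7 genes; camera adjusted p = 0.0156; adjusted p = 0.245 with an estimated correlation; 0.173 without it). Of these, Fgl2 fell from 168 ± 119 to 114 ± 102 CPM (n = 4) and none rose (1 fell adjusted over the list alone). Cell cycle genes were higher without the block (median 0.15 over 21 genes, 0 called; camera adjusted p = 0.0117; adjusted p = 0.413 with an estimated correlation) and not with it (adjusted p = 0.160), nor without YFP-negative or YFP-positive replicate 4 (0.0654 and 0.0546). The remaining lists were called in neither fit. Of 12 lipid handling genes, 1 fell and 0 rose, also adjusted over the list alone. The list was not called (camera adjusted p = 0.677 without and 0.787 with the block). In the lists that follow, no gene passed over all genes tested. Without and with the block, camera's adjusted p was 0.268 and 0.160 for hypoxia and glycolysis, 0.581 and 0.873 for enteric neurons and 0.0626 and 0.666 for mesothelium. It was 0.496 and 0.332 for absorptive enterocytes, and 0.734 and 0.05002 for Paneth cells. It was 0.794 and 0.966 for intestinal stem and progenitor cells, 0.436 and 0.124 for enteroendocrine cells, 0.383 and 0.109 for tuft cells and 0.465 and 0.767 for T and innate lymphoid cells. It was 0.158 and 0.743 for macrophages and dendritic cells, 0.237 and 0.109 for neutrophils, and 0.115 and 0.255 for mast cells. Adjusted over the list alone, 1 gene fell in each of the Paneth, stem cell, enteroendocrine, tuft and T cell lists and 1 rose in the macrophage list. No marker of erythroid cells reached the count filter. The median, mean and test differed in sign in the blocked fit for the lipid, pericyte, interstitial cell of Cajal, mesothelium, Paneth and stem cell lists as well as for the lymphoid organiser list. In the fit without the block they did so for the lymphoid organiser, mesothelium, goblet, Paneth, stem cell, tuft, T cell and interstitial cell of Cajal lists.

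The authors' deposited table gave a log2 fold change for 29762 genes and called 155 genes higher and 341 lower. Its fold changes differed by at most 5.0e-04 from those of DESeq2 with the replicate number as a block, run here on the deposited counts. Of the 111 genes higher and 253 lower in the blocked edgeR fit, 111 and 251 were called in the same direction in the authors' deposited table. Across genes, which are not independent replicates, the log2 fold changes of the authors' deposited table correlated with those of edgeR at 0.991 with the block and at 0.884 without it. For Rapgef5, the blocked edgeR value of 2.95 stood beside 2.94 in the authors' deposited table.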

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

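The tests of a lower fibroblast share, of epithelial cells and of handling between the sort gates were chosen only after the result was seen.

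Of 164 groups of 4 libraries, 13 held a library far from the other 3, against 8.2 that chance alone gives at about 1 in 20. In number 4, the mitochondrial share of the counts was 12.4% in the YFP-negative library (others 8.07% to 8.75%) and 9.43% in the YFP-positive library (others 7.71% to 7.99%), and the 10 most abundant genes took 23.9% of the counts of the YFP-negative library (others 18.0% to 18.4%). In number 3, the complement list stood at a mean log2 CPM of 5.37 in the YFP-positive library (others 5.51 to 5.54) and the pan-leukocyte list at -0.36 in the YFP-negative library (others 1.05 to 1.24). In YFP-negative replicate 1, Map3k14 was at 15.6 CPM (others 36.3 to 37.9) and Mmp12 at 29.3 CPM (others 8.20 to 11.6). In YFP-negative replicate 2, Prkch was at 9.29 CPM (others 2.28 to 2.78), Pde8b at 3.92 CPM (others 12.7 to 13.3) and Ptx3 at 315 CPM (others 47.3 to 64.6). In YFP-positive replicate 2, Ptx3 was at 179 CPM (others 12.4 to 28.2) and Ntrk2 at 103 CPM (others 14.3 to 24.04).

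Epcam stood at 18.3 CPM in YFP-positive replicate 4 (others 0.0800 to 2.62). After thinning to the smallest total, Epcam was at 19.3 CPM there and at most at 2.64 CPM in any other library. These values were computed without TMM factors. Thinning keeps each gene's expected share of the counts, so it cannot decide whether a higher depth of that library was the cause. It shows only that the difference held at the lower depth. Epithelial cells or their RNA in YFP-positive replicate 4 are a candidate source, since 9 of 10 tested epithelium markers had their highest CPM there. Among them were Krt8 at 33.3 CPM (next highest 5.96) and Lgals4 at 32.5 CPM (next highest 17.6), but also Cdh1 at 15.44 CPM (next highest 15.40). Cdh17 was highest in YFP-negative replicate 3, at 24.8 CPM. The sort gated on CD45 and CD31, per the labels, which would not remove epithelial cells, and 1 of the 10 markers stands in another list. No biological explanation was tested.

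The gap between the subepithelial and the adventitial fibroblast lists was 0.88 on the log2 scale in the blocked fit. A trend with GC content or gene length as the whole cause was argued against, because the gap was 0.87 with offsets for both (SD over the 4 pairs 0.193). After thinning to the smallest total the gap was 0.93 (SD 0.176). Thinning keeps each gene's expected share of the counts, so it cannot decide on a difference in depth as the cause. It shows only that the gap held at the lower depth. A lower share of fibroblasts in the YFP-positive libraries would lower both lists alike, and the subepithelial median was 0.28 (SD 0.0866). A lower share as the whole cause would not give this rise, but the rise is part of the pattern itself and no separate test. The pan-fibroblast list was lower in 4 of 4 pairs, with a median of -0.38, so a lower share as a part of the change stays open. Another mix of fibroblast types between the gates, or another state of the same cells, may account for the gap; the bulk libraries do not separate these, and neither was tested.

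The immediate early and heat shock list was lower in the YFP-positive library of 4 of 4 pairs. The blocked median was -0.29 with TMM factors, and its nearest value to 0 under other scalings was -0.21. The SD over pairs was 0.264, larger than that value, so this test leaves scaling open. That SD measures the spread between pairs and not an error of scaling. None of the 4 other scalings brought the median to 0. A scaling factor moves all genes of a library alike, and the median over all tested genes was -0.0029 to 0.091 under these scalings. Handling or time between the sort gates could lower the list in every pair, as seen in 4 of 4, and cannot be told apart from the reporter because each gate is also a group. A biological difference between the groups stays open as well, as untested.

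Other splits of the libraries were compared with the real one. Without the block, the real split called 0 genes, a count that each of the 35 splits matches or exceeds by construction (35 of 35), so the comparison decides nothing. The highest other split called 335 and parted numbers 1 and 2 from 3 and 4, and numbers 1 and 4 against 2 and 3 gave 178. These splits follow the replicate number, a structure of the samples, though numbers 1 and 3 against 2 and 4 gave 0, and the 8 splits that part all 4 pairs called 0. For gene lists without the block, the real split called 16 and 1 of 35 splits, the real one, gave as many, with the highest other at 14. Of those splits 27 do not part all pairs; the 8 that do, where the highest other called 12, are too few for a share under 0.05. With the block there were 8 splits, too few for a share under 0.05. The real split called 364 genes and 26 lists, and the highest other called 0 genes and 20 lists.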

How the results depend on the processing

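The settings within the blocked fit and the pairs of number 2 or 4 left out without it were tests chosen only after the result was seen; the other settings were planned. Without the block, DESeq2 called 0 genes higher and 2 lower, both with an absolute log2 fold change of at least 1, and every other setting without the block called 0 and 0. The replicate block gave 111 higher and 253 lower (8 and 14 at that fold), and 12 lists higher and 14 lower; camera with an estimated correlation and fry called 0 lists higher and 0 lower in both fits. Leaving out single libraries gave 5 to 12 lists higher and 7 to 14 lower. In the blocked fit the genes higher and lower were 212 and 153 with library sizes alone (15 and 7 at that fold), 253 and 420 with no filter (71 and 37), and 221 and 392 with voom (34 and 27). They were 155 and 341 with DESeq2 (31 and 34), and 38 to 130 and 119 to 296 without 1 replicate number (3 to 17 and 7 to 33). At any fold change, more genes were called without number 2 and fewer without each of the others. Lists higher were 6 with the stricter filter, which tests fewer genes, and 7 to 12 without 1 number. Of the results of named genes with the block, 897 were the same, 103 lost their call and 0 reversed; of lists, 276 were the same and 84 lost their call. Epithelium ranged from -0.49 to 0.72 and goblet cells from 0.14 to 2.03 (with the test turned to lower) without 1 number; in both, number 4 turned the direction. Without the block, 626 results of named genes were the same, and 20 were called only with the block. The log2 fold changes that turned with 1 library left out were those of Map3k14 (-0.17 to 0.18), Vcam1 (-0.24 to 0.0053), Cxcl13 (-0.74 to 0.50), Pdpn (-0.30 to 0.028), Epcam (-0.088 to 3.03), and Pecam1 (-0.18 to 0.59), and the Ptx3 log2 fold change (-2.45 to 0.070). Cxcl13 also turned with voom (0.080) and the epithelium covariate (0.089), and Epcam and Pecam1 without both libraries of number 4 (-0.079 and -0.43). The block changed no other call than those given in the report. Unless fewer samples or genes are named, the cause was not tested. The 4 pairs limit small changes: in simulated data of this depth with exact pairing, 49.3% of 1.5-fold changes were recovered with the block.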

Other observations

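The comparison between replicate numbers was chosen only after the result was seen.

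The libraries differed more by replicate number than by reporter. In the blocked edgeR fit, 6270 of 15945 genes differed between the 4 numbers at an adjusted p of 0.05, and number 2 was the highest in 2368 and the lowest in 2687 of them. The genes named here were picked, after their values were seen, from those with the lowest adjusted p in that test. Number 2 was high in Mt1 and Mt2, the metallothioneins, with mean levels of 1778 and 1499 CPM over its pair against 237 to 708 and 144 to 596 CPM in the other pairs. It was also high in the haem oxygenase gene Hmox1 (304 CPM against 38.4 to 83.4), in Txnip (2122 CPM against 382 to 876) and in Fkbp5, a glucocorticoid-induced chaperone gene (360 CPM against 72.4 to 277). It was low in Lpl (55.7 CPM against 150 to 351) and in the collagen chaperone gene Serpinh1 (475 CPM against 722 to 1467). Number 3 was high in Lcn2, the iron-binding protein lipocalin 2 (369 CPM against 32.7 to 234), in Cxcl13 (824 CPM against 167 to 392) and in the interferon-induced chemokine gene Cxcl9 (81.9 CPM against 7.46 to 18.1).

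The share of genes that differed between numbers varied from list to list, beside 6270 of 15945 over all genes tested. All 24 immediate early and heat shock genes differed between numbers, and 15 of them were highest in number 2. Of 21 Wnt, R-spondin and BMP genes, 17 differed and 14 were lowest in number 2. Of 25 interstitial collagen and matrix genes, 23 differed and 13 were lowest in number 2, and of 23 matrix remodelling genes all 23 differed and 12 were highest there. Of 15 complement genes 4 differed, and of 21 cell cycle genes, with a median level of 3.18 CPM, 1 differed. Of 10 MHC class II genes 2 differed and of 11 blood endothelium genes 1, and neither lists nor differences between them were tested. Median levels were 312, 43.5, 1619 and 249 CPM in the immediate early, Wnt, interstitial matrix and matrix remodelling lists. They were 20.2, 3.71 and 14.5 CPM in the complement, MHC class II and blood endothelium lists, so these shares cannot be told apart from expression level. What the replicate number stands for, an animal, a day or a batch, is not given in the sources used here, and no explanation was tested.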
